A study of Mus musculus with 16 samples.

How the data were processed

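RNA of single forebrain cells from CD1 wild-type mouse embryos was measured with the droplet kit of Illumina and Bio-Rad named SureCell, per the labels. The 16 samples share every label, and their titles differ only in 4 numbers crossed with 4 L numbers whose meaning the labels do not give. Values were deposited as 1 matrix of raw counts per gene and cell, against genome build mm10 per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here. The deposited counts are whole numbers with no normalization. The other deposited files hold names, not measurements: gene symbols, and cell names numbered in 1 series with no sample in them, so cells could not be assigned to samples. Before deposit the matrix had been reduced: each of its 14498 genes is in at least 5 cells, the lowest cell has 1111 UMIs, and it holds 0 mitochondrial genes. It holds 98 genes whose symbols start with Rpl or Rps, mainly the prefixes of ribosomal protein genes, with pseudogenes such as Rps19-ps3 among them.

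The comparisons, marker genes, gene lists, size limits, main settings and most alternatives were chosen before the data were examined. Cells needed at least 500 UMIs and at most 10% mitochondrial UMIs, which removed 0 cells, and the mitochondrial limit could not act. Doublets were kept, and their removal by score was an alternative. Counts were scaled to 10000 per cell and log1p transformed. The 2000 most variable genes in at least 10 cells, in 20 bins of mean expression, were the clustering features, and 139 of them are markers. The gene lists, the genes with symbols in Rpl or Rps and the sex genes were left out. Scaled values were limited to 10, and 30 principal components, 15 nearest neighbours weighted by shared neighbours and Leiden resolution 1 (5 iterations, seed 1) gave 20 clusters.

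Cluster names rest on 180 marker genes in 21 lists, 164 of them in the matrix. A cluster took the class with the highest mean log2 marker fold against all other cells, with 10 CPM added. It needed a mean of at least 0.5, at least 3 markers raised 1.5-fold with 10 UMIs, a marker of its class among its 20 leading genes, and among the first 10 no larger number of markers of another class and no such marker in first place. These scoring limits were set later than the markers. Subplate neuron, oligodendrocyte precursor, thalamic, cortical hem, macrophage, endothelial, mural, meningeal fibroblast and erythroid lists named no cluster. Class names mean that cells resemble the class by these markers. After the matrix was read, 4 cells with over 10% globin UMIs (26.5% or more, against 0.191% or less in every other cell) were set apart. The 2 runs of cells were also found only then, from the place of the Y-linked UMIs and of 11 genes out of alphabetical order.

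UMIs were summed over the cells of each class and scaled to the total UMIs of the class (CPM). Genes with at least 50 UMIs over both classes were measured, ratios are of the second class named over the first, and each has an exact conditional binomial (Poisson) 95% interval. A gene with 0 UMIs in a class was set to 3 counts over the class, which gives a lower bound. In 5 comparisons each of 23 gene lists (554 genes, 542 in the matrix) was described by the number of members at least 1.5 times higher or lower and by the median log2 ratio, with a counting interval from 500 Poisson draws. Its place among 10000 random lists of the same size matched on mean expression was taken as outside the range below percentile 2.5 or above 97.5. Random members were drawn independently, so chance places about 5% of lists of unrelated genes there. Lists whose genes vary together can leave the range more often, so the counts of lists outside it are descriptions. Cells of 1 pool are not replicates, hence no p-value was computed. Shares of cells have Clopper-Pearson 95% intervals. For shares of cells with a gene, each cell was thinned at random to 1000 UMIs, which all 5777 cells reach. Positions are those of GENCODE annotation on mm10, 1-based, found for 132 of 134 named genes.

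Genes were named by rule. From a list with at least 1 in 3 measured members past 1.5-fold in a direction, the 2 members with the largest ratio in each direction were named, from other lists the 1 with the largest ratio, up to about 30 per comparison. Genes of the co-detection and sex questions were named as well. Some genes of the lists and 1 planned co-detection question are not reported here. Leading genes of clusters are given as descriptions and were read after clustering.

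Alternatives fixed in advance were no cell filter, a minimum of 1000 UMIs, resolution 0.5 and 2, 15 components, 1000 features, gene lists allowed as features, removal of the 289 cells (5%) with the highest doublet scores, clusters drawn on a random 50% of UMIs with values from the remainder, a minimum of 10 UMIs per gene, equal weight per cell, a 2-fold limit, 500 UMIs or no thinning, and 2 cycle UMIs. Chosen after seeing the data were each run alone, globin-rich cells kept, the 383 features correlated with the cycle lists (r of at least 0.15) left out, every cluster named by its best class, and a limit of 10 cycle UMIs. Alternatives used 2000 random lists.

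Counts were simulated as independent Poisson draws, the model that the intervals assume, with 200 genes changed. Such counts have no spread between cells or runs, so they check the computation only. The intervals held the true ratio for 95.7% of genes in the radial glia against excitatory neuron comparison and 95.3% in the upper against deep layer one. In the former, 98.5% of genes changed 2-fold and 9.09% of those changed 1.25-fold passed the size limit, as did 2.02% of unchanged genes; in the latter 95.2%, 12.3% and 3.51%. Unchanged genes passed in 3.21%, 4.57% and 3.37% for the 3 comparisons between. Of 23 lists, 0 to 2 left the random range in a comparison. Among planted doublets 34.3% of 289 fell in the top 5% of scores, against 3.53% of real cells, so score removal takes out a part of doublets only. Doublet scores came from simulated pairs, 2 per cell, in the manner of Scrublet.

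Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, python-igraph 0.11.9 and matplotlib 3.10.9.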

Results

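Forebrain cells of wild-type CD1 mouse embryos, an outbred strain, were profiled one by one at embryonic day 15.5, when radial glia, intermediate progenitors and young neurons lie side by side in the cortical wall. The 16 samples carry the same strain, genotype, tissue and age, so they form 1 group, and their counts were deposited as 1 pooled matrix. It holds 5777 cells, 14498 genes and 21609944 unique molecular identifiers (UMIs, 1 per captured RNA molecule). The median cell had 3258 UMIs, with a range of 1111 to 17398, and 1784 genes with a UMI. No replicate can be separated in this matrix, so each interval covers counting error only and no value carries a test across embryos.

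The place of the Y-linked UMIs and of 11 genes out of alphabetical order split the matrix into 2 runs of cells. Their absence from 1 of the runs therefore restates that rule in part. Xist, the RNA that silences an X chromosome in female cells, was in both runs, with 4837 and 4532 UMIs. Ddx3y, Eif2s3y, Uty and Kdm5d gave 477, 555, 170 and 161 UMIs, all within the first 3651 cells and none in the last 2122, and 4 cells lie between the runs. A count of 0 among 2122 cells allows up to 0.141% of cells with a Y-linked UMI. The second run alone also held the 241 UMIs of 11 genes listed after the alphabetical order of the others. Median depth was 3162 UMIs in the first run and 3412 in the second. The labels name neither run. Of the 148 gene ratios named below 78 differed by more than 1.5 times between the runs, and only some of them are given for each run.

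Marker genes fixed in advance named 15 of 20 clusters. The excitatory lineage ran from radial glia-like cells with Fabp7, Aldoc and Hopx, through intermediate progenitor-like cells led by Neurog2 and Eomes, to migrating excitatory neuron-like cells with Neurod1, Slc17a6 and Unc5d. In the larger migrating cluster the intermediate progenitor markers Mfap4 (429 against 274 CPM) and Sstr2 (231 against 141 CPM) stood above the intermediate progenitor-like cluster. The other markers of that list stood below it, Eomes at 1118 against 2456 CPM. Older neurons formed a deep layer neuron-like cluster led by Hs3st4, an upper layer neuron-like cluster and an excitatory neuron-like cluster with Bhlhe22 and the deep layer marker Crym. In the upper layer neuron-like cluster 6 of 9 upper layer markers were raised. Cux1, Cux2 and Pou3f3 were not, at 177, 15.8 and 518 CPM. Cux1 and Cux2 stood higher in the Sst and Lhx6 interneuron-like cluster (317 and 83.8 CPM). Pou3f3 stood higher in a migrating excitatory neuron-like cluster (803 CPM), so the upper layer name rests on part of its markers. Rorb, also an upper layer marker, stood higher in the deep layer neuron-like cluster (120 against 80.4 CPM), and the deep layer marker Ldb2 stood lower there (167 against 238 CPM). The ventral forebrain gave ganglionic eminence progenitor-like cells with Olig2 and Gsx2, striatal neuron-like cells with Ebf1, Isl1 and Six3, and interneuron-like cells in an Sst and Lhx6 cluster and an Sp8 cluster. Reln and Trp73 marked Cajal-Retzius cell-like cells, Ttr and Clic6 choroid plexus-like cells, and P2ry12 and C1qc microglia-like cells. These genes helped to draw the clusters, so their levels describe the classes and are not findings about them.

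**Figure D1:**
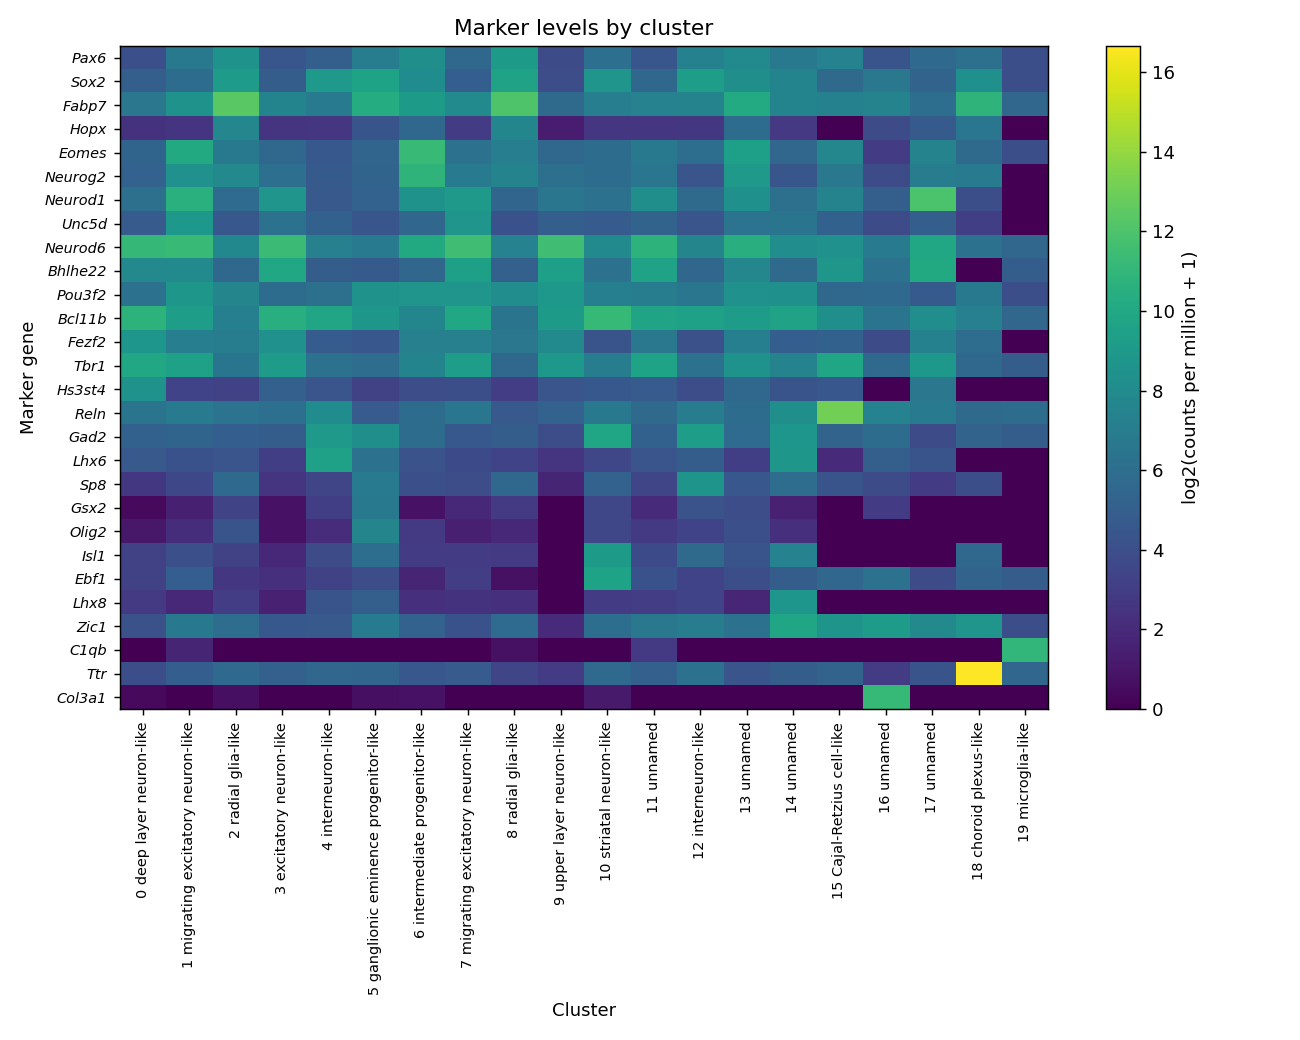
Colour gives log2 of CPM plus 1 for marker genes (vertical axis) in each of the 20 clusters (horizontal axis, with the class name where one was given). Eomes reached 2456 CPM in the intermediate progenitor-like cluster.

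Radial glia-like cells made up 14.02% of all cells (Clopper-Pearson 95% interval 13.1 to 14.9), intermediate progenitor-like cells 7.10% (6.45 to 7.79) and migrating excitatory neuron-like cells 15.8% (14.9 to 16.8). Excitatory neuron-like cells, the 3 older clusters together, made up 24.9% (23.8 to 26.03), including deep layer neuron-like cells at 11.1% (10.3 to 11.9) and upper layer neuron-like cells at 4.76% (4.23 to 5.34). Interneuron-like cells made up 12.2% (11.4 to 13.1), ganglionic eminence progenitor-like cells 8.01% (7.33 to 8.74) and striatal neuron-like cells 4.69% (4.16 to 5.27). Cajal-Retzius cell-like, choroid plexus-like and microglia-like cells made up 1.246%, 0.433% and 0.294%, and 646 cells in 5 clusters stayed unnamed.

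As a share of all cells, radial glia-like cells were alike in the runs, at 13.9% and 14.3%, while the neurons and ventral cells were not. The few ventral cells of the second run raise every other share there. Set against excitatory neuron-like cells, radial glia-like cells were fewer in the second run, 303 beside 754 cells, and 507 beside 684 in the first. Ganglionic eminence progenitor-like cells made up 12.1% of the first run and 0.895% of the second, and striatal neuron-like cells were at 6.90% and 0.848%. Upper layer neuron-like cells showed the opposite, 0.520% (19 cells) and 12.1% (256 cells). Intermediate progenitor-like cells were at 5.12% and 10.5%, deep layer neuron-like cells at 8.24% and 15.98%, and excitatory neuron-like cells as a whole at 18.7% and 35.5%. Interneuron-like cells stood at 12.9% and 10.98%, but their 2 clusters did not differ alike. The Sp8 cluster stood at 5.20% and 1.79%. The Sst and Lhx6 cluster stood at 7.72% (6.88 to 8.64) and 9.19% (7.99 to 10.5), with intervals that overlap. The class is therefore a different mix in each run. The pooled shares therefore average unlike runs, and 9 of the 12 named shares also moved by more than 1.5 times with some clustering choice, for example intermediate progenitor-like cells to 14.5% when genes that follow the cell cycle were kept out of clustering.

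**Figure D2:**
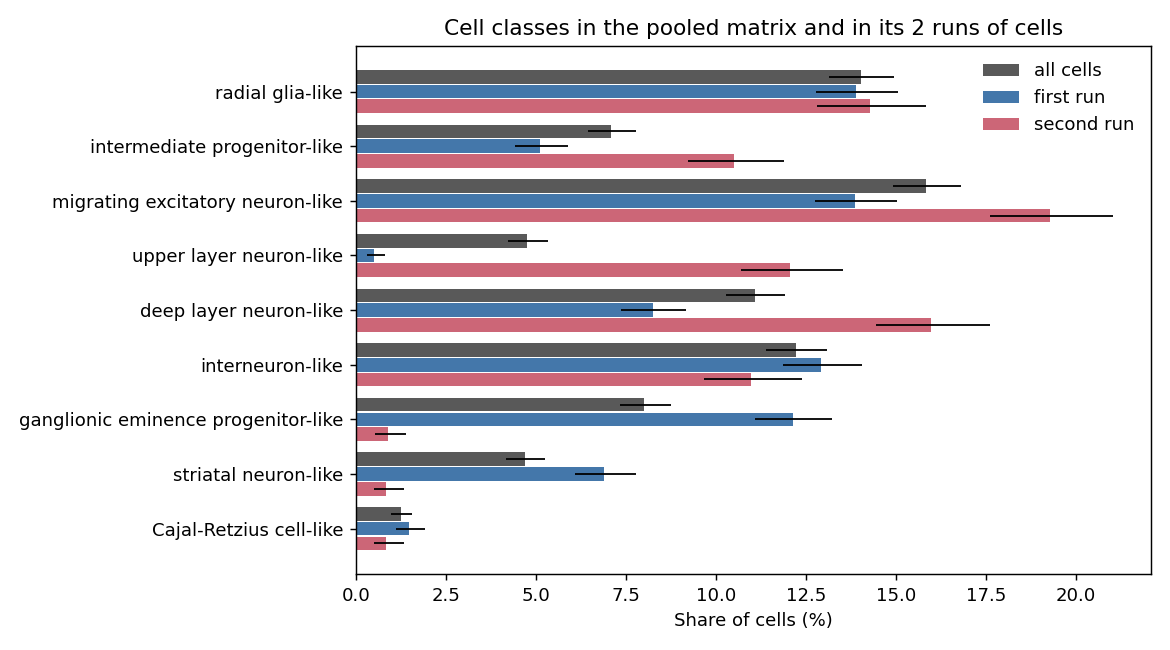
Bars give the share of cells (percent, horizontal axis) in 9 classes for all 5777 cells and for each run, with Clopper-Pearson 95% intervals. Upper layer neuron-like cells reach 12.1% in the second run against 0.520% in the first, and ganglionic eminence progenitor-like cells 0.895% against 12.1%.

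From radial glia-like to excitatory neuron-like cells, the RNA of a dividing progenitor was lower and the RNA of axons, synapses and neuronal splicing was higher. Genes of DNA replication and mitosis were nearly all lower in the neurons, as were most of the Notch, Wnt, FGF, BMP and hedgehog genes. Axon guidance and synaptic genes, neuronal RNA-binding proteins and neuronal subunits of the BAF chromatin remodeller were higher. Of 505 list members measured, 129 were at least 1.5 times higher in excitatory neuron-like cells and 244 at least 1.5 times lower. The medians of 18 of 23 lists lay outside the 95% range of random lists of like expression, 6 above and 12 below, and all 23 kept their sign in both runs; the median over all 10540 genes measured was -0.13.

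The G2/M genes had a median log2 ratio of -4.72 (counting interval -4.90 to -4.57), with 50 of 54 members lower. All 43 S-phase genes were lower, with a median of -3.66 (-3.75 to -3.43). Nusap1, a spindle protein, stood at 223 and 3.43 CPM (counts scaled by the UMIs of the class), 64.9-fold lower (95% interval 42.9 to 103), Gtse1 was 56.9-fold lower, and the S-phase genes E2f8 and Ung were 75.9-fold and 58.6-fold lower. Hn1 was the 1 G2/M gene that was higher, 1.72-fold. Of 22 primary microcephaly genes 17 were lower (median -1.37), including the centrosomal Nde1 at 27.8-fold and the kinesin Kif14 at 40.5-fold. Cell cycle exit genes had a median of -0.64, inside the random range.

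Signalling genes of the progenitor were lower as well. Lfng, a glycosyltransferase that modifies Notch receptors (chromosome 5, 140607320 to 140615545, mm10, 1-based), was 83.2-fold lower (37.6 to 229, with 47.8-fold and 263.5-fold in the runs), and the Notch target Hes1 (chromosome 16, 30064384 to 30067796) 49.4-fold lower (38.4 to 64.5). In the Notch list 13 of 19 genes were lower and 2 higher (median -2.25), Numbl by 2.26-fold and the ligand Dll3 by 1.63-fold. Gli3, a hedgehog transcription factor (chromosome 13, 15463235 to 15730026), stood at 615 and 14.3 CPM, 42.9-fold lower, and Id1 was 37.2-fold lower (19.48-fold and 98.4-fold in the runs), within 15 of 18 lower FGF, BMP and hedgehog genes (median -2.37). Id2, an inhibitor of differentiation, ran against that list at 4.04-fold higher. In the Wnt list 11 of 18 genes were lower (median -2.25), with Sfrp2 at 50.5-fold and Tcf7l1 at 29.4-fold, while Apc and Gsk3b of the complex that degrades beta-catenin were 3.08-fold and 1.60-fold higher.

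Neuronal genes made up most of the higher members. Robo1, the receptor for Slit repellents (chromosome 16, 72308306 to 73046095), was 14.1-fold higher (10.995 to 18.3) and the axonal adhesion molecule Cntn2 13.3-fold higher, among 25 of 34 higher axon guidance genes (median 1.93). The ligands Slit2 and Sema3a were 6.43-fold and 2.57-fold lower. Of 29 synaptic genes 26 were higher (median 2.18), with the vesicle protein Syt4 at 13.6-fold and the kinase Camk2b at 8.71-fold; Camk2a, with 38 and 22 UMIs, was 3.76-fold lower. Neuronal RNA-binding proteins were higher in 16 of 19 (median 1.92), led by Khdrbs2 at 15.03-fold (5.73 to 56.0, from 4 UMIs) and Rbfox1 at 13.3-fold, with Nova1 2.43-fold and Mbnl2 1.60-fold lower. All 6 neuronal BAF subunits were higher (median 2.01), Actl6b by 7.91-fold and Dpf1 by 5.34-fold, and the 7 progenitor BAF subunits had a median of -0.48 inside the random range.

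The remaining lists differed less. Lissencephaly and migration genes had a median of 0.76 with 14 of 24 higher, and autism risk genes 0.37 with 17 of 36 higher. Progenitor RNA-binding proteins stood at -1.31 (9 of 12 lower), extracellular matrix genes at -1.005 (12 of 19 lower, 7 higher), Polycomb repressive complex 2 at -0.80 (5 of 9 lower), glycolysis at -0.74 (10 of 17 lower), immediate early and heat shock genes at -0.65 (9 of 17 lower) and SR and hnRNP splicing factors at -0.49 (11 of 29 lower). DNA methylation genes (-0.60), cholesterol synthesis (-0.47) and nuclear oxidative phosphorylation genes (-0.22) lay inside the random range. All 31 genes named had 1 direction in both runs; Dll3 turned with 15 principal components (-0.072).

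**Figure D3:**
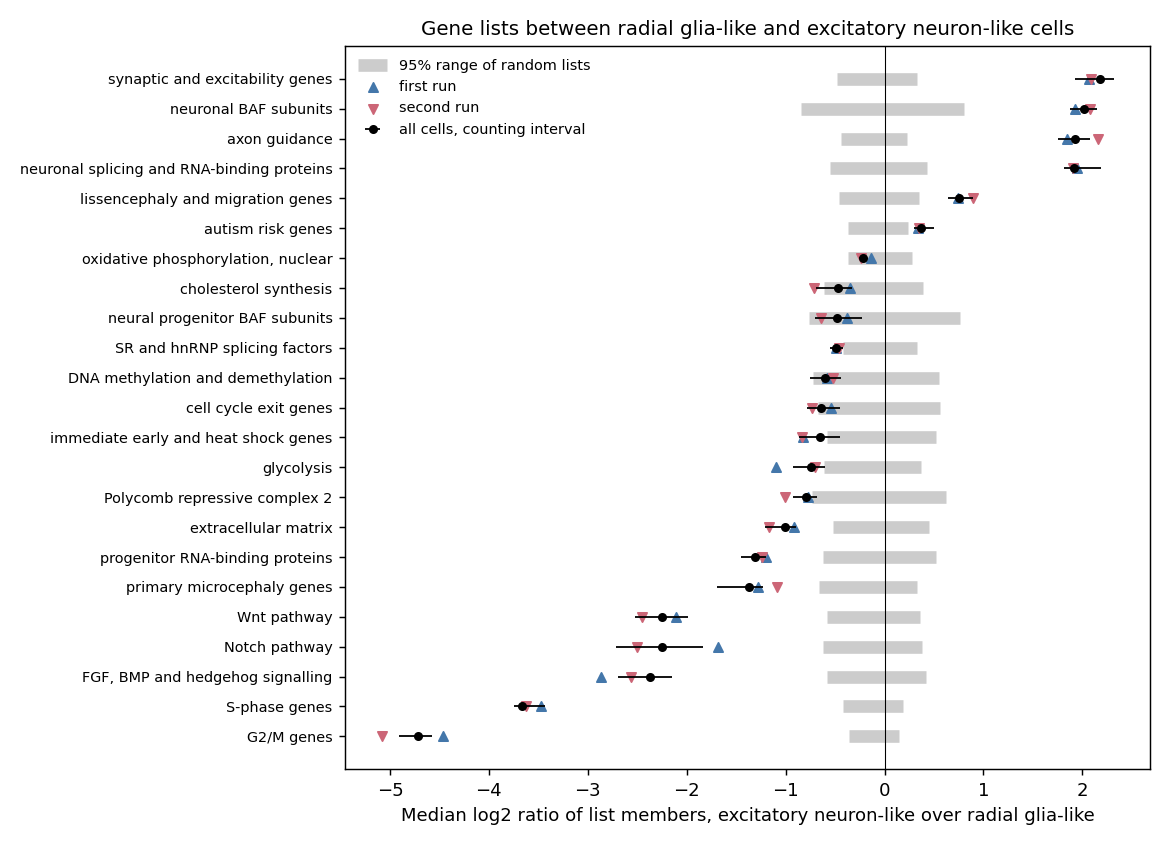
Black points give the median log2 ratio of each of 23 lists, excitatory neuron-like over radial glia-like cells (horizontal axis), with counting intervals; triangles give each run and grey bars the 95% range of random lists. G2/M genes lie at -4.72 and synaptic genes at 2.18, and every list has 1 sign in both runs.

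Intermediate progenitor-like cells had less RNA of the radial glial program and more of several neuronal RNA-binding proteins. Genes of mitosis and DNA replication, FGF, BMP and hedgehog signalling, Wnt signalling and matrix were lower than in radial glia-like cells. Elavl2 and Elavl4, 2 RNA-binding proteins of the Hu family, and guidance receptors such as Dcc were higher. Notch genes as a list did not stand apart, with 5 higher and 8 lower of 19 (median -0.25). Over 479 members, 64 were higher and 187 lower, and 13 of 23 lists lay outside the random range, 3 above and 10 below, each with its sign in both runs and 10 outside the range in each run alone.

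Elavl2, a Hu RNA-binding protein (chromosome 4, 91250763 to 91400785), stood at 160 CPM in radial glia-like and 1396 in intermediate progenitor-like cells, 8.70-fold higher (7.88 to 9.63), and Elavl4 was 7.84-fold higher. They led 8 higher of 16 neuronal RNA-binding proteins (median 0.59), with Nova1 2.03-fold lower. Among 14 higher of 31 guidance genes (median 0.36), the netrin receptor Dcc was 3.60-fold and Plxna2 3.33-fold higher, while Sema6a and Ephb1 were 2.82-fold and 1.82-fold lower. The cell surface proteoglycans Sdc3 and Gpc2 were 5.75-fold and 2.46-fold higher against 9 lower of 16 matrix genes (median -0.73), Sparc by 4.86-fold and Lama1 by 12.1-fold (4.02 to 60.1, 3 UMIs). Autism risk genes had a median of 0.25, with 8 of 34 higher, but lay inside the random range in each run alone, as guidance genes did in the first run.

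Id3, a target of BMP signalling, stood at 160 and 5.999 CPM, 26.6-fold lower (13.4 to 62.0, with 10.62-fold and 86.7-fold in the runs), and Etv5, a target of FGF signalling, was 11.3-fold lower, among 10 lower of 17 genes (median -1.40). Wnt genes were lower in 10 of 18 (median -0.78), the secreted Dkk3 by 14.2-fold and Sfrp2 by 4.55-fold, while Nkd1 was 3.52-fold higher. The G2/M median was -3.61 (50 of 54 lower) and the S-phase median -1.82 (40 of 41 lower). Dlgap5 and Nek2 each had 1 UMI in intermediate progenitor-like cells against 169, 73.3-fold lower with an interval of 12.98 to 2913, and Exo1 and Cdc6 were 47.3-fold (8.31 to 1885, 1 UMI) and 25.2-fold (6.81 to 210.3, 2 UMIs) lower. Microcephaly genes were lower in 14 of 22 (median -1.23), Aspm by 18.5-fold and Wdr62 by 31.7-fold (5.51 to 1268, 1 UMI), with Zfp335 1.64-fold higher. The RNA-binding protein Qk (chromosome 17, 10202601 to 10319854) was 3.33-fold lower (3.03 to 3.66) and Mbnl3 3.53-fold lower, in a list at -0.36 inside the random range.

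Immediate early genes had a median of -0.44 with 6 of 15 lower, Fosb by 9.31-fold and Klf4 by 7.16-fold, though Egr1 and Zfp36 were 1.84-fold and 1.99-fold higher. Cholesterol synthesis stood at -0.38 (-0.17 in the first run, inside the random range), oxidative phosphorylation at -0.21 with all 35 genes between the limits, and SR and hnRNP factors at -0.16. The size of the cycle gene difference depended on where clusters were drawn: the G2/M median was -0.62 at Leiden resolution 2, -1.26 with every cluster named by its best class, -1.45 without cycle-following features and -1.72 with clusters drawn on other UMIs than those measured. At resolution 2 and with best-class naming the S-phase median was -1.16 and -0.99 and the microcephaly median -0.47 and -0.59. The guidance median was 1.003 at resolution 2 and 0.98 without cycle-following features. All 29 genes named kept their direction in both runs and in the alternatives that measured them.

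From intermediate progenitor-like to excitatory neuron-like cells, Notch genes were lower and the genes of axons, synapses and neuronal chromatin were higher. Neuronal BAF subunits, which had not separated radial glia-like from intermediate progenitor-like cells (median 0.23, inside the random range), were higher in the neurons in 5 of 6. Elavl2 and Elavl4, higher in intermediate progenitor-like than in radial glia-like cells, were lower again in the neurons. Of 448 members 114 were higher and 147 lower, and 14 of 23 lists lay outside the random range, 5 above and 9 below, of which 13 kept their sign in both runs and 11 lay outside the range in each run alone.

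Hes5, a Notch target repressor (chromosome 4, 154960923 to 154962371), stood at 646 and 16.7 CPM, 38.6-fold lower (31.7 to 47.4), and the receptor Notch1 was 34.8-fold lower, among 15 lower of 16 Notch genes (median -1.96); Rfng was 1.77-fold higher. Gli2 and Gli3 were 29.3-fold and 13.7-fold lower in the FGF, BMP and hedgehog list at -1.25 (9 of 16 lower, 4 higher), with Id2 3.69-fold and Spry1 10.95-fold higher (1.89 to 440.3, from 1 UMI). Wnt genes stood at -1.48, with Sfrp2 11.1-fold and the receptor Fzd8 10.97-fold lower and Apc 2.95-fold higher; the Wnt median was -0.84 with clusters drawn on other UMIs. Among progenitor RNA-binding proteins (median -1.07), Zfp36l1, which promotes mRNA decay, was 20.6-fold lower and the splicing repressor Ptbp1 4.59-fold lower. S-phase genes stood at -1.25, with Mcm2 8.73-fold and Cdca7 8.04-fold lower, cell cycle exit genes at -0.67 (6 of 10 lower), and G2/M genes at -1.02, with Hmgb2 5.49-fold and Cenpa 3.40-fold lower.

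Synaptic genes were higher in 21 of 27 (median 2.04), Camk2b by 11.1-fold (7.63 to 16.7) and the NMDA receptor subunit Grin1 by 21.1-fold (3.71 to 841, from 1 UMI). Dpf1 and Actl6b were 12.9-fold and 5.20-fold higher (BAF median 1.65). Guidance genes were higher in 24 of 34 (median 1.16), Cntn2 by 15.4-fold and the growth cone protein Gap43 by 9.86-fold, while Slit2 and Epha4 were 5.40-fold and 2.57-fold lower. Of 19 neuronal RNA-binding proteins 12 were higher (median 1.16); Rbfox1 (chromosome 16, 5885355 to 7411526) by 15.5-fold and Khdrbs2, with 0 UMIs in intermediate progenitor-like cells, by at least 8.69-fold at a floor of 3 counts over the class, while Elavl4 and Elavl2 were 3.54-fold and 2.93-fold lower. Migration genes stood at 0.78 (13 of 24 higher) and glycolysis at -0.53 (8 of 17 lower, 6 higher), with -0.26 in the first run, inside the random range, and -0.79 in the second. Matrix genes, at -0.60 over all cells, stood at 0.24 in the first run and -0.00 in the second, so this list gives no direction. The S-phase median was -2.43 at resolution 2 and -2.41 with best-class naming. The G2/M median ranged from -0.29 in the second run, inside the random range, to -3.51 at resolution 2, where Tubb4b and Rangap1, 2.87-fold and 2.31-fold higher over all cells, stood at -0.027 and -0.12 on the log2 scale.

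Excitatory neuron-like and interneuron-like cells, the output of the cortical wall and of the ventral forebrain, differed in glycolysis, cholesterol synthesis and guidance genes in each run. Cell cycle and synaptic genes lay outside the random range over all cells and in the first run and inside it in the second. Interneuron-like cells had more RNA of the presynaptic adhesion molecule Nrxn3 and the AMPA receptor subunit Gria4, and less of Camk2b and the synaptic adhesion gene Nlgn1. In glycolysis 10 of 17 genes and in cholesterol synthesis 7 of 17 were at least 1.5 times lower, with none of either list 1.5 times higher. Of 449 members 88 were higher and 81 lower in interneuron-like cells. Over all cells 11 of 23 lists lay outside the random range, 6 above and 5 below. In the second run alone 5 did, 3 of these 11 and, higher there, neuronal RNA-binding proteins (0.24) and immediate early genes (0.36), and 7 did with clusters drawn on other UMIs.

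Nrxn3 (chromosome 12, 88722876 to 90334935) stood at 18.4 and 631 CPM, 34.4-fold higher in interneuron-like cells (28.5 to 41.8), with 19.9-fold and 81.2-fold in the runs. Gria4 was 5.97-fold higher, Camk2b 5.04-fold and Nlgn1 4.51-fold lower, within 7 higher and 11 lower of 28 synaptic genes (median -0.39, with -0.56 and -0.087 in the runs, the latter inside the random range). Of 35 guidance genes 14 were lower and 6 higher (median -0.37), with Cntn2 9.35-fold lower, Plxnd1 13.98-fold lower (3.78 to 117, 2 UMIs, with 14.37-fold and 1.44-fold in the runs), and Unc5c and Sema3a 2.47-fold and 2.40-fold higher. Ldha, which makes lactate (chromosome 7, 46841475 to 46855627), was 4.26-fold lower (3.60 to 5.08) among 10 lower of 17 glycolysis genes (median -0.79); Hk2 was 4.34-fold lower but turned to 0.15 on the log2 scale without cycle-following features. Fdps and Mvd were 2.02-fold and 1.999-fold lower (cholesterol median -0.56), and Smarcd3 and Smarca2 1.62-fold and 1.54-fold lower (neuronal BAF median -0.45).

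Cycle genes were higher in interneuron-like cells, G2/M genes in 22 of 35 (median 1.08) and S-phase genes in 16 of 29 (median 0.69), with Cdca7 12.8-fold, Gmnn 3.20-fold, Fam64a 4.10-fold and Aurkb 4.01-fold higher. The G2/M median was 0.56 and 0.11 and the S-phase median 0.73 and 0.23 in the runs, both inside the random range in the second. It was 0.12 for G2/M genes with clusters drawn on other UMIs, 0.37 with 15 principal components and 3.01 without cycle-following features. No ganglionic eminence progenitor-like cluster formed in these alternatives. Without cycle-following features interneuron-like cells made up 16.1% of cells, against 12.2%, with a cycling share of 79.6%. The 3.01, and the values of Hk2 and Maml2 there, are thus of a differently drawn class. Etv1, a transcription factor, was 21.8-fold higher (12.9 to 39.0), Notch1 5.48-fold, Dll3 2.05-fold and Qk 4.57-fold, with Hey1 3.01-fold lower. The Notch and FGF, BMP and hedgehog medians, 0.37 and 0.36 over all cells, were -0.21 and -0.23 in the second run and give no direction. SR and hnRNP factors stood at 0.25 and progenitor RNA-binding proteins at 0.34, and neither these nor the BAF list left the random range in the second run. Inside the random range, the medians of the autism (0.03) and Wnt (0.08) lists had means of the other sign, -0.24 and -0.31. Sparcl1 and Lamb1 of the matrix list were 13.3-fold and 6.16-fold lower and Gpc1 1.60-fold higher, and Dnmt3a, a DNA methyltransferase, was 2.45-fold and Dpf2 1.77-fold higher; Hnrnph2 stood at 1.42-fold and Maml2 at 1.55-fold lower (0.876 to 2.96), which turned to 0.36 without cycle-following features.

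Deep layer neuron-like cells had more synaptic and matrix RNA, and less RNA of cholesterol synthesis, than upper layer neuron-like cells. Of the upper layer neuron-like cells 256 of 275 lie in the second run, against 339 of 640 deep layer neuron-like cells, so ratios over all cells mix layer with run. Vcan, a matrix proteoglycan (chromosome 13, 89655312 to 89742509), stood at 105 CPM in upper and 588 in deep layer neuron-like cells, 5.61-fold higher (4.70 to 6.75) and 4.06-fold in the second run, and Gpc4 was 2.31-fold higher (2.22-fold). The AMPA receptor subunit Gria3 (chromosome X, 41400854 to 41678601) was 6.17-fold higher (4.14 to 9.58) and 5.60-fold in the second run. Of 378 members 49 were higher and 36 lower, and 8 of 23 lists lay outside the random range, 4 above and 4 below, each with its sign in both runs, but 3 of the 8 lay outside it in the first run alone, 5 in the second and only neuronal BAF and matrix genes in each. In the first run, with wider random ranges, the synaptic and cholesterol medians were 0.302 and -0.31, just inside.

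Matrix genes had a median of 0.35 (4 of 11 higher, 0.35 in the second run), synaptic genes 0.31 (7 of 26 higher, 0.348 in the second run) and neuronal RNA-binding proteins 0.22 (0.17, inside the random range), where Celf4 was 3.03-fold higher. Smarcd3 and Smarca2 were 2.09-fold and 1.68-fold higher (neuronal BAF median 0.37), both lower in interneuron-like than in excitatory neuron-like cells. Cholesterol synthesis stood at -0.64 (-0.57 in the second run) with 8 of 15 genes lower, Fdps by 2.14-fold and Msmo1 by 1.92-fold. Jun and Klf6 were 2.17-fold and 1.88-fold lower, but the immediate early median, -0.38 over all cells, was -0.11 and -0.20 in the runs, inside the random range of each. SR and hnRNP factors stood at -0.25 (-0.23 in the second run) and progenitor RNA-binding proteins at -0.26 (-0.16, inside the random range). From the remaining lists, Plxnd1 was 8.55-fold (3.20 to 32.2, 4 UMIs), Btg2 2.01-fold, Eno2 1.97-fold, Mbd4 1.97-fold, Rbl2 1.73-fold and Uqcrh 1.39-fold higher, and the lipid transporter Mfsd2a 4.58-fold, Fzd1 2.79-fold, Lamb1 1.92-fold and Hnrnph2 1.59-fold lower. In the second run Btg2, Uqcrh and Hnrnph2 stood at 1.32-fold, 1.198-fold and 1.24-fold. Igf2bp2, Maml2, Ss18, Spry2, Top2a, Rrm2, Ezh1 and Shank3 also came under the naming rule, but their direction differed between the runs. The first run holds 19 upper layer neuron-like cells. At resolution 0.5, which drew other layer classes, 4 lists lay outside the random range.

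Cell cycle RNA was counted per cell to ask which classes divide. After thinning to 1000 UMIs, 96.8% of radial glia-like cells (95.3 to 97.9) and 99.4% of ganglionic eminence progenitor-like cells had at least 3 UMIs of the S-phase and G2/M lists, against 99.9% and 100% unthinned. That rule did not separate dividing cells: 60.9% of excitatory neuron-like cells (58.3 to 63.5), which should not divide, passed it too, as did 62.2% of upper and 57.2% of deep layer neuron-like cells. The shares of intermediate progenitor-like (76.3%), interneuron-like (72.2%), striatal neuron-like (70.1%) and migrating excitatory neuron-like cells (67.2%) lay little above that background. At 10 UMIs, a limit set after this was seen, the shares were 72.1% (68.9 to 75.2) for radial glia-like, 88.1% for ganglionic eminence progenitor-like, 8.78% for intermediate progenitor-like, 4.39% for interneuron-like, 2.62% for migrating excitatory neuron-like and 0.834% for excitatory neuron-like cells. In the 2 runs these were 13.37% and 4.93% for intermediate progenitor-like, 6.14% and 0.858% for interneuron-like, 3.36% and 1.71% for migrating excitatory neuron-like and 1.32% and 0.398% for excitatory neuron-like cells. The unnamed cluster of 206 cells, whose best class was intermediate progenitor, stood at 69.9%, so the intermediate progenitor-like share depends on where that cluster was drawn. The clustering features held 383 genes that follow the cycle lists, and without them no ganglionic eminence progenitor-like cluster formed. Top2a was among the leading genes of that cluster and of 1 radial glia-like cluster. The high shares of these classes therefore restate in part how the clusters were drawn. The lists took 1.79% of radial glia-like, 2.35% of ganglionic eminence progenitor-like, 0.483% of intermediate progenitor-like and 0.326% of excitatory neuron-like UMIs.

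Eomes, the transcription factor that marks intermediate progenitors (chromosome 9, 118478212 to 118486132), was looked for together with neuronal identity genes in the same thinned cells. Its UMIs were in 83.9% of intermediate progenitor-like cells (80.0 to 87.3), 33.0% of migrating excitatory neuron-like, 7.41% of radial glia-like and 3.41% of excitatory neuron-like cells. Interneuron-like cells, which should lack it, showed 3.40% at a median of 2252 UMIs before thinning, against 3028 in intermediate progenitor-like cells (unthinned shares 5.81% and 97.6%). At equal depth the excitatory neuron-like share was thus level with that of interneuron-like cells; unthinned it was 8.76%, at a median of 4499 UMIs, and free RNA and low expression were not told apart.

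Over the named classes of the excitatory lineage, 755 cells had an Eomes UMI and 2818 had none. The unnamed cluster of 206 cells, led by cell cycle genes and with Eomes at 661 CPM, is not among them. Shares of cycle RNA beside Eomes therefore leave its cells out. Neurog2, a proneural factor, was in 48.3% of Eomes-positive cells (44.7 to 52.0) and 9.76% of the others, and Neurod1, which follows Eomes in the lineage, in 37.6% (34.1 to 41.2) and 17.4%. Pax6 stood at 19.9% and 10.8% and Sox2 at 14.4% and 14.2%. The layer identity genes were less frequent beside Eomes: Bcl11b in 25.96% and 45.7%, Tbr1 in 27.2% and 34.6%, and Fezf2 in 12.98% and 19.5%. Cux2 was near its floor at 1.46% and 0.923%, below the 6.37% of interneuron-like cells. Mki67 and Top2a stood at 2.52% and 4.37% beside Eomes and 5.15% and 10.9% without it, and the share with 3 cycle UMIs was 72.5% and 72.4%. Background, the share in a class that should lack the gene, was Neurog2 in 2.41%, Neurod1 in 2.83%, Tbr1 in 5.24% and Fezf2 in 2.27% of interneuron-like cells, Bcl11b in 8.64% of radial glia-like cells, and Pax6 in 1.252%, Sox2 in 2.57%, Mki67 in 0.487% and Top2a in 1.599% of excitatory neuron-like cells, at medians of 2252, 3350.5 and 4499 UMIs before thinning.

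Classes differ in all these genes, so the same was asked within a class. In migrating excitatory neuron-like cells, Neurod1 was in 66.2% of 302 Eomes-positive and 45.0% of 613 Eomes-negative cells, Neurog2 in 25.2% and 11.9%, and Bcl11b in 33.8% and 51.9%. Tbr1 was level at 45.4% and 45.5%. This class joins 2 clusters, and 286 of the 302 Eomes-positive cells lie in 1 of them, of 547 cells. Within it Bcl11b was in 33.2% (27.8 to 39.00) and 47.1% (40.9 to 53.4). Neurod1 was in 67.5% (61.7 to 72.9) and 61.3% (55.1 to 67.2), so most of the Neurod1 difference lies between the clusters. Neurog2 stayed more frequent beside Eomes, at 26.2% (21.2 to 31.7) and 16.9% (12.5 to 22.0), with intervals that overlapped by little. In intermediate progenitor-like cells, Neurod1 (20.1% of 344 and 16.7% of 66), Tbr1 (13.7% and 15.2%) and Bcl11b (17.4% and 15.2%) differed within counting error. Over all named classes of the excitatory lineage, Bcl11b beside Eomes was in 34.0% of cells of the first run and 18.6% of the second, against 48.0% and 42.9% without Eomes.

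**Figure D4:**
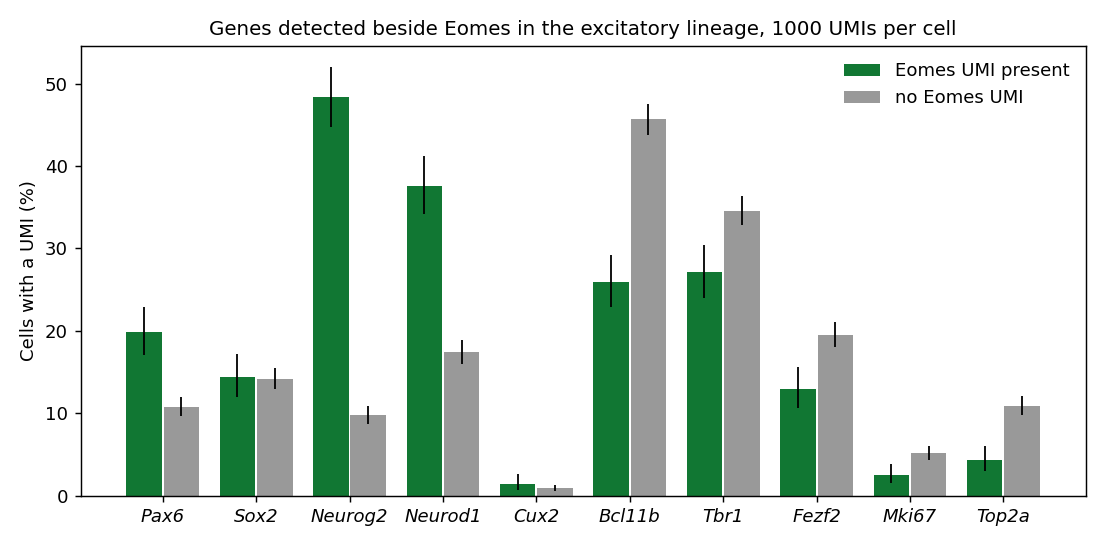
Bars give the percent of cells in the named excitatory lineage classes with a UMI of each gene (vertical axis) among 755 cells with and 2818 cells without an Eomes UMI, each thinned to 1000 UMIs, with Clopper-Pearson 95% intervals. Unnamed clusters are left out. Neurog2 stands at 48.3% and 9.76%, and Bcl11b at 25.96% and 45.7%.

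Sex-linked RNA showed cells of both sexes in the first run. Xist (chromosome X, 103460366 to 103483254) was in 63.2% of all cells (61.9 to 64.4), a Y-linked UMI in 13.6% (12.8 to 14.6) and both in 4.55% (4.03 to 5.12). In the first run 54.9% of cells had Xist, 21.6% a Y-linked UMI and 7.20% both. Xist was in 33.4% of Y-positive cells (30.1 to 36.8) and 60.8% of the other cells of that run. The second run had Xist in 77.3% and Y-linked RNA in none of 2122 cells. Cells with both kinds of RNA hold free RNA or a second cell, and the share does not tell these apart.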

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

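Each run alone, globin-rich cells kept, cycle-following features left out, naming by best class and the limit of 10 cycle UMIs were tried only after the data had been seen; all other alternatives were planned. Class names here stand for the -like classes, shares are percent of cells, and where a value moved the cause was not tested unless the text gives it. No paired analysis was possible because all samples form 1 group and cells carry no sample number. The cell filter and the minimum of 1000 UMIs remove 0 cells, so these settings say nothing about stability. The progenitors of the ganglionic eminences had no cluster at resolution 2, with 15 components, with clusters drawn on separate UMIs and without cycle-following features, and Cajal-Retzius and choroid plexus cells had none with 15 components, so these settings give no value for them.

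Leaving out settings that could not move them, of 1827 values of named genes 1453 stayed within the counting interval, 365 moved and 9 were counted as reversed. Of 1610 list medians these numbers were 1330, 274 and 6, and of 435 shares, counts and co-detection values 297 stayed and 138 moved. These counts do not hold every change of sign. The 6 are all of lists outside the random range over all cells. Both runs gave the same sign for 23, 20, 20, 16 and 20 of 23 lists, in the order below. Of the layer genes whose direction differed between the runs, only Ss18 and Rrm2 are among the 9. Lists outside the random range numbered 17 to 19 for radial glia against excitatory neurons, 10 to 15 for radial glia against intermediate progenitors, 12 to 16 for intermediate progenitors against excitatory neurons, 5 to 16 for excitatory neurons against interneurons and 4 to 9 for upper against deep layer neurons. Members past the size limit ranged from 306 to 392, 182 to 272, 200 to 312, 101 to 247 and 40 to 156 in the same order.

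At resolution 0.5 the shares were 17.0% radial glia, 19.1% migrating, 26.5% excitatory, 6.18% upper layer and 20.3% deep layer neurons, 8.31% interneurons and 8.45% striatal neurons; 4 lists lay outside the random range between the layers, and the FGF, BMP and hedgehog median of interneurons over excitatory neurons turned to -0.051. At resolution 2 they were 10.5% radial glia, 11.5% intermediate progenitors, 14.6% migrating and 22.0% excitatory neurons; the cycling share of intermediate progenitors was 83.0%, and between intermediate progenitors and excitatory neurons Tubb4b turned to -0.027 and Rangap1 to -0.12.

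With 15 principal components, radial glia stood at 16.6%, upper layer neurons at 4.19%, deep layer neurons at 14.1% and striatal neurons at 6.92%, and Dll3 turned to -0.072 between radial glia and excitatory neurons. With 1000 variable genes, the shares were 13.1% radial glia, 8.01% intermediate progenitors, 14.7% migrating neurons, 13.4% interneurons, 4.41% progenitors of the ganglionic eminences and 1.16% choroid plexus cells, and the cycling shares of radial glia and of the ganglionic eminence class were 98.0% and 95.7%. With report lists in the features, they were 15.1% radial glia, 16.3% excitatory, 7.91% upper layer and 8.36% deep layer neurons, 13.4% interneurons and 2.87% for the ganglionic eminence class, whose cycling share was 94.6%.

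Without the top 5% of doublet scores, intermediate progenitors stood at 8.31%, migrating neurons at 14.6% and choroid plexus cells at 1.22%. With globin-rich cells kept, migrating neurons stood at 9.47%, because the cluster of 368 cells no longer met the naming limits.

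With clusters drawn on separate UMIs, the shares were 18.1% radial glia, 12.5% intermediate progenitors, 12.3% migrating, 28.8% excitatory and 7.11% upper layer neurons, 8.29% interneurons, 7.75% striatal neurons and 0.952% choroid plexus cells. Between excitatory neurons and interneurons 7 lists lay outside the random range, and the Notch and FGF, BMP and hedgehog medians turned to -0.047 and -0.15. The cycling shares at 500 UMIs were 85.9% for radial glia, 39.3% for intermediate progenitors, 27.3% for migrating, 23.0% for excitatory, 23.4% for upper layer and 23.0% for deep layer neurons and 31.9% for interneurons.

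Without cycle-following features, radial glia stood at 9.33%, intermediate progenitors at 14.5%, migrating neurons at 10.5%, excitatory neurons at 29.2%, upper layer neurons at 5.85% and interneurons at 16.1%; the cycling share of interneurons was 79.6%, and Hk2 and Maml2 turned to 0.15 and 0.36 between excitatory neurons and interneurons. With every cluster named by its best class, intermediate progenitors stood at 10.7% with a cycling share of 83.6% and excitatory neurons at 28.9%, and Rangap1 and Tubb4b stood at -0.068 and -0.00054 between them.

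In the first run alone, intermediate progenitors stood at 5.12%, migrating neurons at 13.9%, excitatory neurons at 18.7%, upper layer neurons at 0.520%, deep layer neurons at 8.24%, the ganglionic eminence class at 12.1% and striatal neurons at 6.90%. Cycling shares were 82.4% for intermediate progenitors, 70.6% for migrating, 64.5% for excitatory, 68.4% for upper layer and 61.1% for deep layer neurons. Beside Eomes, Bcl11b was in 34.0%, Tbr1 in 31.5% and cycle RNA in 76.8% of cells. The matrix median of excitatory neurons over intermediate progenitors turned to 0.24, and between the layers 5 lists lay outside the random range (4 against 10000 random lists) and Ss18 and Rrm2 turned to -0.20 and -0.059, with 19 upper layer neurons.

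In the second run alone, the shares were 10.5% intermediate progenitors, 19.3% migrating, 35.5% excitatory, 12.1% upper layer and 15.98% deep layer neurons, 10.98% interneurons, 0.895% for the ganglionic eminence class and 0.848% each for striatal neurons and Cajal-Retzius cells. Cycling shares were 95.05% for radial glia, 71.3% for intermediate progenitors, 63.1% for migrating and 57.7% for excitatory neurons, 67.8% for interneurons and 100% for the 19 cells of the ganglionic eminence class. Beside Eomes, Bcl11b was in 18.6%, Tbr1 in 23.2% and cycle RNA in 68.4%. Between excitatory neurons and interneurons 5 lists lay outside the random range, and the Notch and FGF, BMP and hedgehog medians turned to -0.21 and -0.23.

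The 2-fold limit left 101 members between excitatory neurons and interneurons and 40 between the layers, by its construction, and a minimum of 10 UMIs per gene raised the latter to 156 by measuring more genes.

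Depth set the shares of cells with a gene. Thinned to 500 UMIs, cycling shares were 86.2% for radial glia, 33.4% for intermediate progenitors, 29.8% for migrating, 21.8% for excitatory, 22.5% for upper layer and 22.3% for deep layer neurons, 35.1% for interneurons and 93.5% for the ganglionic eminence class. Beside Eomes, Neurod1 was in 27.1%, Bcl11b in 14.9%, Tbr1 in 17.0% and cycle RNA in 34.8%. Not thinned, cycling shares were 99.9%, 96.8%, 97.5%, 98.0%, 98.5%, 96.9%, 97.0% and 100% in that order, Neurod1 beside Eomes was in 56.2%, Bcl11b in 52.4%, Tbr1 in 53.1% and cycle RNA in 97.5%.

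A limit of 2 cycle UMIs gave 87.8% for intermediate progenitors, 86.3% for migrating, 80.9% for excitatory, 79.6% for upper layer and 78.6% for deep layer neurons and 88.7% for interneurons. A limit of 10 gave 72.1% for radial glia, 8.78% for intermediate progenitors, 2.62% for migrating, 0.834% for excitatory, 1.09% for upper layer and 0.469% for deep layer neurons, 4.39% for interneurons and 88.1% for the ganglionic eminence class.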

Other observations

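The tests of depth, of ventral marker RNA, of dissection, of upper layer markers, of doublets and of cycling cells of 1 lineage, and the choice of genes named from unnamed clusters, were made only after the result was seen; those of upper layer markers and of doublets replaced earlier forms whose results were known by then. The tests of sex and of a shift between the runs were written down first, but the repeat of the latter on genes with at least 50 UMIs and the share of the Sp8 cluster were added later.

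Among the clusters without a class name, 151 cells carried transcription factors of the ventral and medial forebrain. Lhx8, needed for cholinergic neurons of the basal forebrain, reached 428 CPM against 7.07 in all other cells, with Zic1 at 897, Zic4 at 374, Nkx2-1 at 349 and Gbx2 at 108 CPM. They made up 4.14% of the first run and 0 of 2122 cells of the second, and mixed markers of 2 classes kept them unnamed. Another 234 cells (4.05%) had Fam19a2, Nts and Nr2f2 in front, with Neurod6 at 1744 and Tbr1 at 809 CPM, so they carried excitatory neuron RNA without an excitatory marker among their leading genes. Nr2f2, a factor of caudal cortex, stood there at 832 CPM against 149 elsewhere. A group of 26 cells had the retinoic acid degrading enzyme Cyp26b1 at 546 and the calcium binding protein Calb2 at 417 CPM, with Neurod1 at 3960 CPM.

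Vascular and meningeal RNA met in 29 cells (0.502%) with Col4a1 at 4189, Igf2 at 4476, Col3a1 at 2273, Dcn at 1159, the pericyte gene Pdgfrb at 369 and the endothelial gene Cldn5 at 267 CPM, which kept this cluster unnamed. In 17 microglia-like cells Ccl3 stood at 3800 CPM and Apoe at 7051, beside P2ry12 at 3192. Striatal neuron-like cells had the neuropeptide gene Tac1 at 192 CPM. Of 5037 genes measured in 5 classes in both runs, 4 were at least 2 times higher in the second run in every class, Dtx3 (median log2 1.85), Gapdh (1.71), Rbm3 (1.32) and Ppia (1.27), and 5 lower, Rps19-ps3 (-2.74), Mir682 (-2.46), Gm6548 (-2.34), Dlx6os1 (-2.22) and Gm12657 (-1.67). Gapdh is also in the glycolysis list.

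Ganglionic eminence progenitor-like, striatal neuron-like and Lhx8 cells were nearly missing from the second run. Depth argues against a loss of detection, since the median UMIs of the second run were 1.079 times those of the first, and the summed RNA of 15 ventral markers over all cells, 467 and 64.5 CPM, a ratio of 0.1381 (0.126 to 0.151), argues against ventral cells hidden in other clusters. Sex does not account for it either: ganglionic eminence progenitor-like and striatal neuron-like cells made up 20.32% (18.5 to 22.3) of 1742 first-run cells with Xist and no Y-linked UMI, against 1.74% (1.23 to 2.40) of the second run. A dissection with less ventral tissue may be the source, but this was not decided. The share of the Sst and Lhx6 cluster, cells of a kind that migrates into cortex, was 1.19 times as high in the second run. The highest of the 3 ventral clusters was at 0.123 times, which sets them apart by a factor of 9.681. The Sp8 interneuron-like cluster lay between, at 0.344 times. The 3 clusters were picked because they were nearly missing and the shares were known, so this factor restates the pattern and cannot test dissection. The labels describe no dissection, and apart from sex no biological explanation was tested because the design has 1 group.

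Upper layer neuron-like cells were nearly missing from the first run. If a shift of RNA common to all classes had made this cluster, the median log2 change of its 20 leading genes should reach 1 in radial glia-like, deep layer neuron-like and migrating excitatory neuron-like cells alike, but it was 0.4732 (0.265 to 0.556), 0.213 (0.0770 to 0.299) and 0.308 (0.229 to 0.420), and at most 0.509 (0.309 to 0.634) over those with at least 50 UMIs. Such a shift therefore does not account for the whole of the pattern, though a smaller one is present in these genes. Over all excitatory neuron-like cells 8 upper layer markers had a median log2 change of 0.6907 (0.569 to 0.848), but that class holds the cluster itself, so this value restates the pattern and does not decide whether the first run had fewer upper layer neurons. That, and age or position of the sampled tissue, stays open, and the design gives no group to test it.

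The unnamed cluster of 206 cells led by cell cycle genes such as Bub1b and Top2a had the highest median depth among clusters of over 100 cells, 5426 UMIs, and 55.3% of its cells had doublet scores in the top 5%. Cycling progenitors of 1 lineage were predicted to keep Neurod6 far below its level in excitatory neuron-like cells. It stood at 1400 CPM, 0.5592 of that level, and Pax6 at 0.517 of its level in radial glia-like cells. Intermediate progenitor-like cells, the best class of this cluster, themselves had Neurod6 at 1116 CPM and Pax6 at 310 CPM. The test therefore cannot tell cycling intermediate progenitors from a mix of lineages. Doublets may be the source: Xist was in 35.29% (14.2 to 61.7) of 17 Y-positive first-run cells of the cluster after thinning, against 11.97% of 309 elsewhere, and unthinned in 57.1% of 49 against 31.8%. With 17 cells the interval is wide, and progenitors that keep neuronal RNA while dividing were not tested.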
